A study of Mus musculus with 2 samples.

How the data were processed

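Cells from infarcted mouse brain, 3 days after transient middle cerebral artery occlusion, were profiled as BD Rhapsody single-cell RNA-seq libraries, 1 from flox and 1 from Hilpda cKO mice. The number of animals per library is not given in the sources used here. The deposited values are raw UMI counts per gene and barcode, whole numbers with no normalization. CASAVA 1.8, STARsolo, Seurat and the genome build mm10 are named in the submitters' processing notes. The gene annotation, the counter's settings and the cell caller are not given in the sources used here. The lowest total of any barcode was 500 UMIs in both libraries, and the highest was 33705 in flox and 38731 in cKO. Of 31253 features, 31107 had their identifier in GENCODE vM21, which supplied coordinates on GRCm38 and the last 500 nt of each gene's transcript.

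Cells were kept with at least 500 UMIs, at least 200 genes and at most 25% mitochondrial UMIs. The mitochondrial limit removed 274 flox and 242 cKO barcodes and the gene limit 52 and 25. Scrublet, as run in scanpy 1.11.5 on each library with an expected rate of 6%, marked 231 flox (2.79%) and 143 cKO (2.01%) cells as doublets, which were left out. The median mitochondrial share of the kept cells was 6.19% and 6.05%.

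Kept cells of both libraries were clustered together without integration. Counts were scaled to 10000 per cell and log-transformed, the 2000 most variable genes were used without Hilpda and without sex-linked, mitochondrial, ribosomal and haemoglobin genes, and 30 principal components gave a shared-neighbour graph of 20 neighbours. Leiden clustering (leidenalg 0.10.2, igraph 0.11.9) at resolution 1 gave 28 clusters. Clusters were named with "-like" from fixed markers of 22 classes, with 4 to 11 markers each. The markers were written before the data were examined, but the thresholds of the naming rule were revised after the clusters were seen, so the share of unnamed cells is given for each library. In all, 25 clusters fell into 13 named classes and 3 stayed unnamed. The 7 classes with at least 100 cells in each library were compared.

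UMIs were summed over the cells of a class and library and expressed as CPM of that sum. Ratios are cKO over flox on the log2 scale with exact conditional 95% intervals, levels have exact Poisson intervals and shares exact Clopper-Pearson intervals. These intervals cover counting error only. With 1 library per group no test was made. The size rule asked for at least a 2-fold difference, at least 30 UMIs and 100 CPM in the higher library, and an interval that excluded equal levels. A gene at 0 UMIs in a library was set against a floor of 3 counts.

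For each of 28 fixed gene lists the median log2 ratio was taken over members with at least 10 UMIs in the class, where at least 5 members qualified. Its percentile came from 10000 random lists of the same size, matched on expression in 25 bins, and medians under the 2nd or over the 98th percentile were called extreme. These percentiles describe the 2 libraries and are not tests. The interferon list was used without Mx1 and the disease-associated microglia list without Clec7a, which were not analysed here.

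The genes named were set by a rule written before the data were examined. It takes the 10 highest and 10 lowest ratios past the size rule in all cells, microglia-like and macrophage-like cells, the 3 highest and 3 lowest in each other class, Hilpda, and from each extreme list 2 to 4 members with the highest summed count, of which some are not reported here. Sex-linked, mitochondrial, ribosomal and haemoglobin genes were treated as groups, and gene models were left out. Lyz2, Ly6c2, Ftl1, the genes set beside C1qa and Ctsd, and the genes in the closing observations were chosen after their values were seen. For the share of cells with a Hilpda UMI, cells were thinned to 1000 UMIs.

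Results were recomputed under alternatives of the cell filters, doublets, resolution, depth, scaling (the trimmed mean of M-values, TMM, from edgeR 4.0.16 in R 4.3.3), weight of cells and count filters. Not every result was run under each. Resolution 0.5 was run for gene lists and shares, resolution 2 for these and for gene counts, and thinning of cells for shares alone. Hilpda and other single genes were not recomputed under these 3 settings. Further alternatives chosen after the data were seen were the ratio of a class relative to the median of the other compared classes, subtraction of the median of genes of like 3′ GC in 10 bins, clustering without 2180 genes that were at least 1.41-fold apart in the median of the classes, and macrophage-like cells without the cluster led by interferon-induced genes. The Hilpda subsets came from that clustering without shared genes.

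The calculations were tested on simulated counts drawn from the real levels, with counting error and no variation between cells or libraries. The changed genes were taken from those at 200 CPM or more, or 50 CPM or more in every class for the class-relative ratio. Recovery of such genes checks the calculation and says nothing about variation between libraries. The size rule recovered 50 of 50 genes at 3-fold and at 4-fold in each direction in microglia-like (16139 genes), macrophage-like (16107), oligodendrocyte-like (14556) and neutrophil-like cells (10567). It passed 0 unchanged genes in the first 3 of these and 16 in neutrophil-like cells. Lists moved 1.3-fold reached percentiles of 99.8 to 100, and an unmoved list in microglia-like cells was at 2.46. The class-relative ratio found 200 of 200 genes moved in macrophage-like cells alone and 0 of 200 genes moved in all classes, over 11260 genes. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.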

Results

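The data were single-cell RNA-seq counts (BD Rhapsody) from infarcted mouse brain at day 3 after transient middle cerebral artery occlusion, a model of ischaemic stroke. A single library came from floxed control mice, which the design text also calls WT, and a single library came from mice with a conditional knockout (cKO) of Hilpda. The flox library held 8593 barcodes with 67864602 UMIs and a median of 6852 UMIs per barcode. The cKO library held 7382 barcodes with 70665440 UMIs and a median of 8513 UMIs. After filtering, 8044 flox cells (median 6999 UMIs and 2476 genes) and 6983 cKO cells (median 8747 UMIs and 2762 genes) were kept. Y-linked Ddx3y was present in both libraries at 79.6 and 74.0 CPM, and the X-inactivation transcript Xist had 1 and 0 UMIs, a male pattern in both. With 1 library per group there was no replicate check, library preparation cannot be told apart from group, and every interval below covers counting error only. No tests were made, and each difference below is between 2 libraries.

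The first question was where Hilpda RNA lay in the infarct and how its level compared between the libraries. Hilpda (ENSMUSG00000043421, chromosome 6:29272488–29275446, plus strand, GRCm38) encodes a lipid droplet protein that inhibits the triglyceride lipase Pnpla2 and is induced by hypoxia. In flox its highest level was in monocyte or macrophage-like cells, at 472 CPM, and in that class it stood at 267 CPM in cKO (log2 ratio −0.82, 95% interval −0.86 to −0.78; 14585 and 8564 UMIs). Microglia-like cells went the other way, with 101 CPM in flox and 225 CPM in cKO (1.16, 1.09 to 1.24; 2229 and 4619 UMIs). Neutrophil-like cells had 205 and 33.0 CPM (−2.64, −3.61 to −1.76), but from only 50 and 14 UMIs, and the monocyte markers Plac8 (−3.00) and Ly6c2 (−1.89) were lower in the same class. The summed Hilpda level was also higher in cKO in dendritic cell-like cells (129.5 and 190.25 CPM, 0.55, 0.27 to 0.84). The intervals of their shares of positive cells, given below, overlapped. In border-associated macrophage-like cells the summed level was 68.1 and 129 CPM (0.93, 0.61 to 1.25), which the share of positive cells below did not follow. Endothelial cell-like cells (53.8 and 57.5 CPM, 0.10) and oligodendrocyte-like cells (45.1 and 36.0 CPM, −0.32) had intervals that included 0. Over all cells the level was 273 CPM in flox and 214 CPM in cKO (−0.35). Most flox macrophage-like cells lay in cluster 0 and most cKO ones in cluster 1, while for microglia-like cells the clusters holding the most cells were 4 in flox (842 of 2124) and 6 in cKO (667 of 1401).

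The share of macrophage-like and microglia-like cells with at least 1 Hilpda UMI had the same order at equal depth. With every cell thinned to 1000 UMIs, the share was 26.7% in flox and 14.1% in cKO for macrophage-like cells, and 6.80% and 13.1% for microglia-like cells. Before thinning the shares were 63.3% and 35.4% in macrophage-like cells and 35.2% and 56.4% in microglia-like cells, at median depths of 8014 and 10212 UMIs and 9173 and 14571 UMIs. Cells under 1000 UMIs were left out, 10 flox and 8 cKO macrophage-like and 5 and 1 microglia-like. As a background, choroid plexus epithelial cell-like cells had thinned shares of 1.75% and 3.01% (5.48% and 6.92% before thinning), at median depths of 3730.0 and 5636 UMIs. Neuroblast-like cells in cKO had 0 positive of 67 thinned cells (upper limit 5.36%), and 8.97% of them were positive before thinning. In neutrophil-like cells the thinned share was 15.4% in flox and 3.81% in cKO, where it was near that background. In border-associated macrophage-like cells the thinned shares of 8.24% and 5.49% went against the summed CPM values, so neither library was taken as higher in that class. Dendritic cell-like cells had thinned shares of 10.6% (7.27% to 14.8%) in flox and 12.5% (8.74% to 17.3%) in cKO, with overlapping intervals. The counted 3′ tag of Hilpda may lie outside the deleted part of the gene, and the labels give neither the deleted exons nor the Cre driver. The Hilpda level therefore checks nothing about the genotype of either library.

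**Figure D1:**
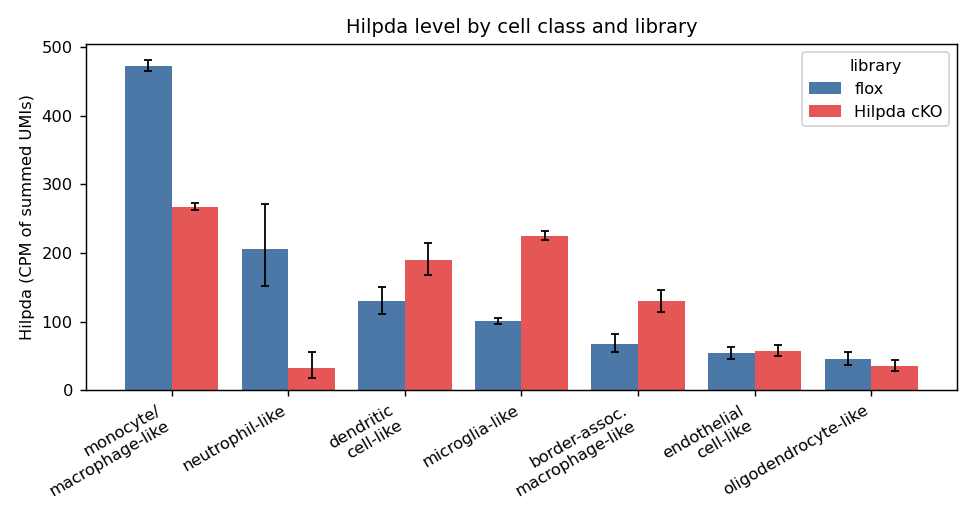
Hilpda level in CPM of summed UMIs for 7 cell classes in the flox (blue) and Hilpda cKO (red) libraries, with 95% counting intervals. The macrophage-like level was 472 CPM in flox and 267 CPM in cKO, and the microglia-like level was 101 and 225 CPM.

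The direction of Hilpda within the myeloid classes depended in part on how subsets were made. In the main clustering, macrophage-like clusters 0, 1, 13 and 27 were lower in cKO (−1.36, −0.46, −0.30 and −0.98), and cluster 2, with 656 flox and 857 cKO cells, was level at 264 and 275 CPM (0.06, −0.06 to 0.18). Microglia-like clusters 3, 5 and 6 were higher (0.75, 1.03 and 1.24), while cluster 4, the largest in flox, was lower at 128.9 and 77.6 CPM (−0.73, −1.12 to −0.37), with only 63 cKO cells. Clusters 0, 1, 4 and 6 came mostly from 1 library each. Subsets were therefore also made, after the data were seen, by clustering without 2180 genes whose median ratio over the classes was at least 1.41-fold. Among macrophage-like cells, the subset led by Fabp4 and Gpnmb, which encode a fatty acid carrier and a lysosomal glycoprotein of lipid-laden cells, had the most Hilpda, at 696 CPM in flox and 322 CPM in cKO (−1.11). The subset led by Il10 and Nr4a3 had 399.95 and 189 CPM (−1.08), the Il18bp and Mgst1 subset had 337 and 169 CPM (−0.99) and the F10 and Ccr2 subset had 453 and 304 CPM (−0.57). Only the Plac8 and Ly6c2 subset was level at 239 and 226 CPM (−0.08, −0.23 to 0.07). Among microglia-like cells, the Mmp12 and Lpl subset had 177 and 322 CPM (0.86), the Gpr84 and Ccl12 subset 52.3 and 101 CPM (0.94), and the Siglech and P2ry12 subset, with genes of resting microglia, 15.8 and 31.0 CPM (0.97). Cycling cells followed their class, at −1.21 in macrophage-like and 1.02 in microglia-like cells.

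**Figure D2:**
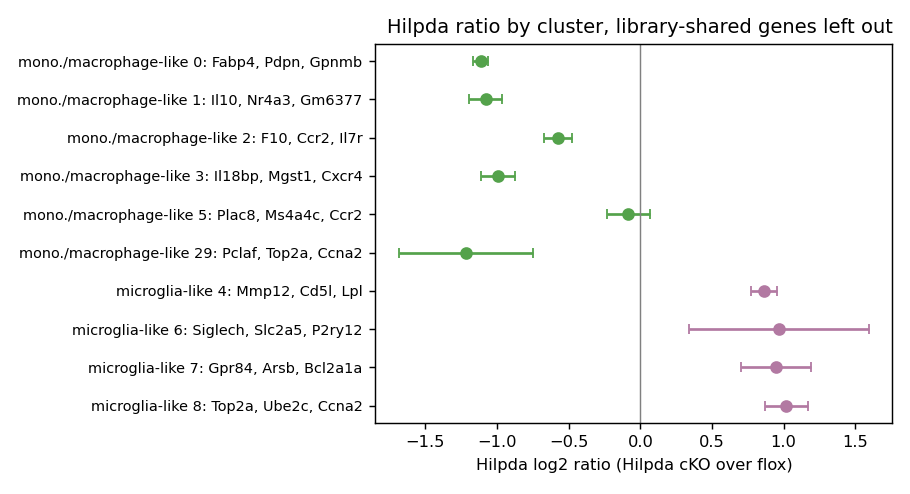
Hilpda log2 ratio of cKO over flox (horizontal axis) for each cluster of monocyte or macrophage-like (green) and microglia-like (purple) cells, with 95% counting intervals. The Fabp4 and Gpnmb cluster was at −1.11, the Plac8 and Ly6c2 cluster at −0.08 and the Mmp12 and Lpl cluster at 0.86.

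The second question was the make-up of the infarct. Monocyte or macrophage-like cells were the largest class, at 44.5% of flox cells (43.4% to 45.6%) and 43.3% of cKO cells (42.1% to 44.4%). Microglia-like cells, the resident myeloid cells of the brain, were 26.4% (25.4% to 27.4%) and 20.1% (19.1% to 21.02%). Neutrophil-like cells were 2.56% and 4.38%, choroid plexus epithelial cell-like cells 0.908% and 2.28%, fibroblast-like cells 0.361% and 1.46%, and astrocyte-like cells 0.783% and 1.53%. Smaller differences separated the endothelial cell-like (7.01% and 7.79%), oligodendrocyte-like (4.202% and 4.998%), dendritic cell-like (3.56% and 3.67%) and border-associated macrophage-like (2.34% and 2.76%) shares. Neuroblast-like cells made up 0.783% and 1.12%, oligodendrocyte precursor-like cells 0.659% and 0.573%, and ependymal cell-like cells 0.460% and 0.401%. Cells in unnamed clusters were 5.49% and 5.70%. How tissue was taken and dissociated also acts on such shares, and 1 library per group leaves that unmeasured.

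**Figure D3:**
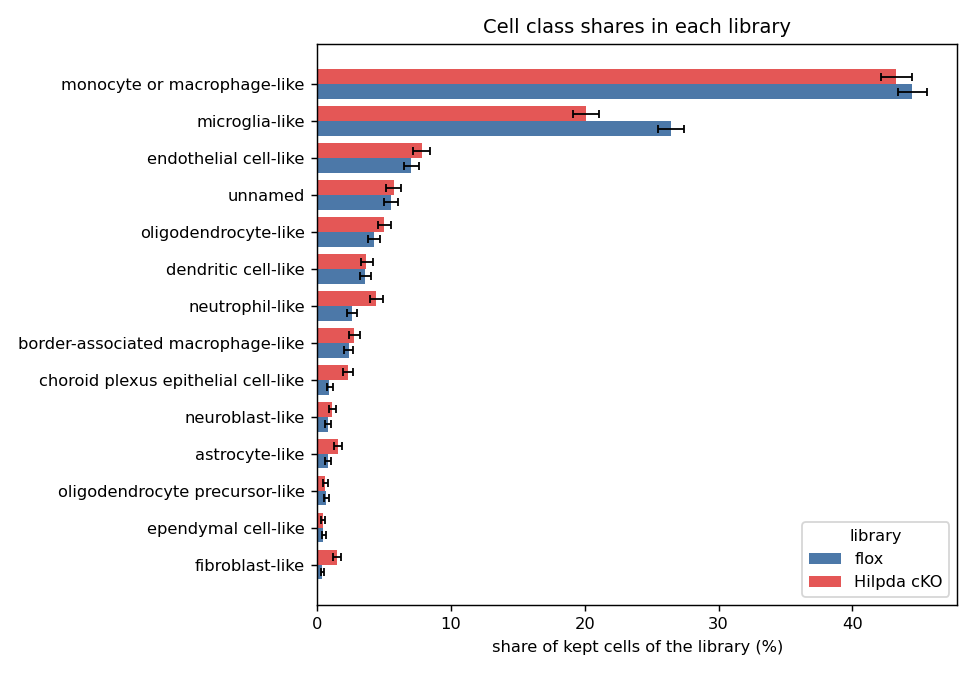
Share of kept cells (%) in each cell class for the flox (blue) and Hilpda cKO (red) libraries, with exact 95% counting intervals. Microglia-like cells were 26.4% in flox and 20.1% in cKO.

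Across all cells pooled, 4 genes passed the size rule as higher in cKO and 68 as lower. The higher genes were Gfap, the intermediate filament of astrocytes (59.7 and 161 CPM, log2 ratio 1.43), Enpp2, which makes lysophosphatidic acid (333 and 729 CPM, 1.13), Ttr, the thyroxine carrier secreted by choroid plexus (1207 and 2532 CPM, 1.07), and Ptgds, a prostaglandin synthase of the meninges and choroid plexus (65.5 and 135 CPM, 1.04). Gfap is an astrocyte marker and Ttr a choroid plexus marker, and the shares of both cell classes were higher in cKO. Enpp2 was also among the top genes of the choroid plexus epithelial cell-like cluster. Among cells with at most 10% mitochondrial UMIs Gfap stayed past 2-fold (1.71), while Enpp2 (0.61), Ttr (0.46) and Ptgds (0.32) did not. The lower genes were led by the G protein subunit Gnb2 (192 and 15.8 CPM, −3.61), the early response gene Ier2 (304 and 41.6 CPM, −2.87), the complement subunit C1qa (1467 and 221 CPM, −2.73), the lipid peroxide reductase Gpx4 (−2.72), the ferritin copy Ftl1-ps1 (−2.58), Bin1 (−2.51), Eif5a (−2.36), Grina (−2.31), Gas6 (−2.26) and the lysosomal hexosaminidase subunit Hexa (−2.21). Gnb2 and Eif5a were past the size rule in all 7 compared classes, Ier2 and Hexa in 6 and C1qa in 5.

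These lower genes shared a sequence property. Of 9011 genes with at least 30 UMIs in 4 or more compared classes, 332 were at least 2-fold lower in cKO in 4 or more of them, endothelial cell-like or oligodendrocyte-like cells included, and 3 were higher, and the last 500 nt of the transcript had at least 50% GC in 88.3% of the lower genes against 23.6% of all 9011. Their median 3′ GC was 56% against 43.4%. In macrophage-like cells the median log2 ratio was 0.04 at 40 to 45% GC, −0.39 at 55 to 60% and −1.15 at 60% and above, and in oligodendrocyte-like cells it was −0.30 and −0.68 in the latter 2 bins. In neutrophil-like cells the median did not follow this at 55 to 60%, with 0.01 over 66 genes. It was −0.33 over only 5 genes at 60% and above. The share of genes at least 2-fold lower in that class was however 15.2% at 55 to 60%, against 1.71% at 50 to 55%. Not every gene above 50% GC was lower. In macrophage-like cells C1qa (chromosome 4:136895917–136898803; 3′ GC 58%) was at −2.65 beside its partners C1qb (53.6%) at 0.25 and C1qc (52.8%) at 0.08. The ferritin light chain Ftl1 (57.8%) was at −2.08 beside the heavy chain Fth1 (46.6%) at 0.33, and the lysosomal protease Ctsd (56.4%) at −1.61 beside Ctsb (49.6%) at −0.02. These shared genes made up 96.6% of the lower genes in macrophage-like cells, 91.2% in microglia-like cells and 44.3% in neutrophil-like cells. Ftl1 and Ftl1-ps1 are near-identical copies, so reads may be placed on either.

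**Figure D4:**
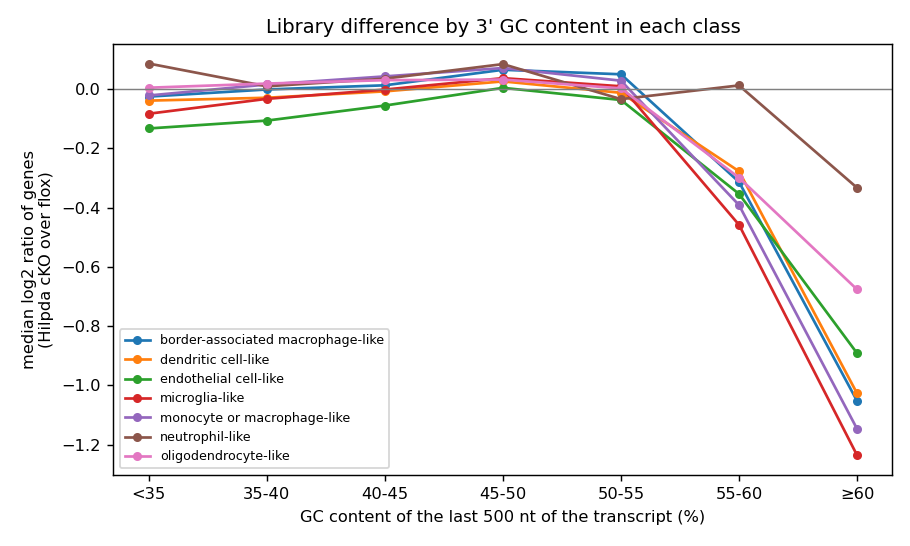
Median log2 ratio of genes (cKO over flox) against the GC content of the last 500 nt of the transcript (%), with 1 line per compared class. At 60% GC and above the median was −1.24 in microglia-like and −0.68 in oligodendrocyte-like cells.

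In microglia-like cells the question was whether resident myeloid cells differed between the libraries, and 4 genes were higher and 68 lower in cKO. Saa3 (chromosome 7:46711998–46715700), an acute-phase lipoprotein component, was at 34.95 and 107 CPM (1.61, 1.49 to 1.73). Lgals3 (chromosome 14:47367751–47386160), a galectin of phagocytes that take up debris, was at 1239.6 and 2731 CPM (1.14), and the secretory kinase Fam20c at 51.4 and 106 CPM (1.04). Hilpda itself, given above, was the remaining higher gene. Lower genes were the endoplasmic reticulum isomerase Fkbp2 (103 and 4.43 CPM, −4.53), Gnb2 (−3.80), the GPI transamidase subunit Pigt (−2.89), Ier2 (−2.74), C1qa (−2.61), Bin1 (−2.47), Ftl1-ps1 (−2.45), Eif5a (−2.44), Grina (−2.33) and the coactivator Edf1 (−2.21). Fkbp2 was at least 2-fold lower in all 6 classes where it was measured (median −4.31), although below 100 CPM elsewhere, and each other gene was past the size rule in at least 1 other class, Gnb2 and Eif5a in all 6 others.

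Of 27 gene lists in microglia-like cells, 5 were extreme on the low side and 5 on the high side among random lists. Fatty acid uptake and binding was higher (median 0.45, percentile 100), with Fabp5, a fatty acid carrier, at 0.57 and the scavenger receptor Msr1 at 0.48, although the lipoprotein receptor Lrp1 was at −1.99. Fatty acid oxidation was also higher by its median (0.20, percentile 99.6; Hadha 0.32 and Cpt1a 0.16), although its mean was −0.03. Repair-associated genes (0.31, percentile 99.9; Socs3 0.74, Igf1 0.22 and Il4ra −0.77), antioxidant genes (0.22, percentile 99.4; Gpx1 0.29 and Prdx1 0.14) and genes first described in reactive astrocytes (0.49, percentile 100; Vim 0.49 and Cd14 0.32) were the others. On the low side, homeostatic genes had a median of −0.49 (percentile 0), although the abundant members named here, Cst3 (0.24) and Csf1r (0.23), were higher. Among clusters made without the shared genes, the resting subset led by Siglech and P2ry12 held 663 flox and 235 cKO cells. The mix of states thus differed too, which these list medians do not separate from a change within a state. The interferon response was at −0.35 (percentile 0.0200; Bst2 −0.03 and Ifi27l2a −0.67), but at −0.16 with equal weight per cell and 0.13 relative to the other classes, so it was not lower than in them. Also low were glycolysis and hypoxia response at −0.19 (percentile 0.920; Gapdh 0.23, Aldoa 0.07, Pgam1 0.26 and Pgk1 −0.07) and immediate early and heat shock genes at −0.44 (percentile 0; Zfp36 0.15, Egr1 −0.36 and Fos −0.32). Neutrophil granule genes, markers of another class, were at −0.83 (percentile 0.895; Mmp8 0.63, S100a9 −0.92 and S100a8 −0.33).

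In monocyte or macrophage-like cells, which enter the infarct from blood, only Lyz1 was past the size rule as higher, at 10.04 CPM in flox and 174 CPM in cKO (4.12, 3.95 to 4.29). Its neighbour Lyz2 (ENSMUSG00000069516, chromosome 10:117277331–117282321, minus strand), the main lysozyme of macrophages, was at 16991 and 7943 CPM (−1.10). Lyz1 (chromosome 10:117287797–117292868) and Lyz2 are near-identical copies, so the split of reads between them is uncertain. The 58 lower genes were led by Gnb2 (192 and 16.6 CPM, −3.53), Ier2 (−3.03), Gpx4 (120 and 17.0 CPM, −2.82), Cyp4f18, which inactivates leukotriene B4 (151 and 22.6 CPM, −2.75), C1qa, Ftl1-ps1 (−2.56), Amdhd2 (−2.53), Eif5a (−2.36), Grina (−2.28) and Gas6, a ligand for clearing dead cells (−2.23). Each was past the rule in at least 1 other class.

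Among 27 lists in macrophage-like cells, 8 were low and 2 high. The interferon response was at −0.53 (percentile 0; Ifitm3 −0.15, Bst2 −0.19 and Ifi27l2a −0.49), but the cluster led by the interferon-induced Rsad2, Slfn4 and Ifit3 held 266 flox and 81 cKO cells, and the median was −0.31 without it and −0.078 relative to the other classes. Next were inflammatory cytokines and chemokines at −0.18 (percentile 0.0900; Cxcl2 −0.08, Nfkbia −0.01, Nlrp3 −0.18 and Il1b −0.18). Fatty acid synthesis was at −0.33 (percentile 0.415; Scd2 −0.32 and Elovl5 0.06) and glycolysis and hypoxia response at −0.10 (percentile 1.69; Gapdh 0.28, Aldoa 0.25, Pgam1 0.30 and the angiogenic factor Vegfa −0.47). The NADPH oxidase list was at −0.20 (percentile 1.17; Cybb −0.22, Cyba −2.14 and Rac2 0.27), homeostatic microglia genes at −0.32 (percentile 0.0300; Cst3 0.45 and Csf1r 0.41) and immediate early and heat shock genes at −0.45 (percentile 0; Zfp36 0.00, Fos −0.61 and Hspa8 0.05). Neutrophil granule genes, markers of another class, were at −1.13 (percentile 0; Mmp8 0.26, S100a8 −0.15, S100a9 −2.73 and Ngp −7.48). Higher lists were the antioxidant response (0.22, percentile 99.4; Gpx1 0.22, Prdx5 0.69 and the haem oxygenase Hmox1 0.71) and the cell cycle (0.18, percentile 98.9; Pcna −0.02, Hmgb2 0.03, Stmn1 −0.04 and Mki67 0.46). Relative to the other classes the medians of glycolysis (0.049), homeostatic genes (0.068), NADPH oxidase (0.000274) and the antioxidant response (−0.017) had the opposite sign and lay near 0.

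Border-associated macrophage-like cells, the class of the meninges and vessel walls, addressed the same question outside the parenchyma, with 8 genes higher and 70 lower. The cholesterol exporter Abcg1 was at 68.1 and 221 CPM (1.70), the TNF-induced gene Tnfaip2 at 56.5 and 163 CPM (1.53) and Lgals3 at 307 and 744 CPM (1.27), the latter also higher in microglia-like and oligodendrocyte-like cells. The lower genes were led by Gnb2 (−4.13), Ftl1-ps1 (−3.09) and Ier2 (−2.83), all shared with other classes. Of 26 lists 8 were high: fatty acid uptake and binding (0.60; Cd36 −0.20, Fabp5 0.90 and Lrp1 −1.44), cholesterol efflux and storage (0.25; Apoe 0.11, Npc2 −0.02 and Abca1 0.40), inflammatory cytokines and chemokines (0.28; Cxcl2 0.21, Ccl4 0.31, Ccl2 −0.30 and Ccl7 −0.53), disease-associated microglia (0.25; Ctsb 0.11 and Apoe 0.11), MHC class II (0.40; Cd74 0.34 and H2-Aa 0.21), antioxidant response (0.24; Hmox1 0.18, Gpx1 0.24 and Prdx1 −0.13), neutrophil activation (0.56; Ccl4 0.31, Ccl3 0.07 and Ccrl2 1.17) and activated endothelium (0.54; Vcam1 −0.21, Icam1 0.54, Lrg1 −0.86 and Selp 1.61), the last a list of another class. The MHC class II median changed sign among cells with at least 1000 UMIs (−0.41). Immediate early and heat shock genes were low at −0.21 (Zfp36 0.08, Jund 0.04, Hspa8 0.13 and Egr1 −0.49), but at 0.10 relative to the other classes, where the activated endothelium median was −0.10.

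Dendritic cell-like cells, which present antigen, had 1 gene higher and 52 lower. The higher gene was the adrenomedullin coreceptor Ramp3 (120 and 261 CPM, 1.12), and the lower ones were led by Gnb2 (−4.29), the LIM protein Csrp1 (−3.30) and C1qa (126 and 19.8 CPM, −2.67). The interferon response was low at −0.72 (Ifitm3 −0.01, Ifi27l2a −0.57 and Oasl2 −0.47), as were immediate early and heat shock genes at −0.52 (Zfp36 −0.14, Hspa8 −0.14 and Nr4a1 −0.89). The antioxidant response was high at 0.35 (Gpx1 0.20, the superoxide dismutase Sod1 0.49 and Prdx1 −0.03), but at −0.031 relative to the other classes.

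Neutrophil-like cells, which reach the infarct first, had 37 genes higher and 70 lower, at median depths of only 1062 and 1292 UMIs. The cochaperone Stip1 (53.4 and 186 CPM, 1.803), the matrix protein Adamtsl4 (37.0 and 125 CPM, 1.76) and the granule protein Ltf (57.5 and 193 CPM, 1.75) were higher, each from fewer than 100 UMIs. The cystatin-like genes Stfa1 (234 and 18.9 CPM, −3.63) and Cstdc5 (139.7 and 11.8 CPM, −3.57), and Plac8, a marker of monocytes here (226 and 28.3 CPM, −3.00), were lower. The low lists were the interferon response (−0.88; Ifitm3 −0.74 and Oasl2 −0.21), lipolysis (−0.70; G0s2 −0.12, Lipa 0.21 and Pnpla2, the lipase that Hilpda inhibits, −1.37), glycolysis and hypoxia response (−0.26; with its abundant members Aldoa 0.17, Gapdh 0.16, Pgam1 0.19 and Ldha 0.30 on the other side), NADPH oxidase (−0.41; Rac2 0.10, Ncf1 −0.82 and Cybb 0.27), the cell cycle (−1.22; Hmgb2 −0.30, Pcna −0.05, Mki67 0.02 and Stmn1 −1.75) and neutrophil granule genes (−0.35; S100a9 −0.68, S100a8 −0.32 and Mmp9 0.10). The lipolysis median was the value of Abhd5 (−0.70, −1.85 to 0.46, from 14 and 15 UMIs), and Pnpla2 was at least 2-fold lower in all 7 compared classes. The granule list was split, with Ltf (1.75), Camp (2.31, 0.61 to 4.68, from 3 and 26 UMIs) and Ngp (0.85, 0.47 to 1.25) higher in cKO.

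In endothelial cell-like cells the question was whether the vessel wall differed, and 11 genes were higher and 92 lower. P-selectin (Selp), which captures leukocytes from blood, was at 157 and 478 CPM (1.61, 1.46 to 1.76), the neutrophil attractant Cxcl1 at 61.5 and 163.5 CPM (1.41) and the siderophore-binding protein Lcn2 at 49.2 and 128 CPM (1.38). The activated endothelium list was high at 0.86 (Lrg1 −0.24, Vwf −0.01, the venular chemokine receptor Ackr1 1.002 and the adhesion molecule Icam1 1.23), and the blood-brain barrier list low at −0.46 (the glucose transporter Slc2a1 −0.46, Pecam1 0.31 and the tight junction protein Cldn5 −2.47). The make-up of the class differed as well, since among clusters made without the shared genes a cluster led by Spock2 and Slco1a4 held 212 flox and 80 cKO cells and a cluster led by Ctla2a and Egfl7 held 62 and 116. Also high were the cell cycle (1.18; Pcna 0.23, Stmn1 0.21 and Mcm3 −0.16), reactive astrocyte genes (0.26; Vim 0.35, Tm4sf1 0.40 and Hspb1 −0.21) and, by its median of 0.18 though not its mean of −0.16, oxidative phosphorylation (Cox6c 0.40, Cox7c 0.30 and Cox6a1 −0.11). The named cell cycle members and Hmgb2 (0.52) lay below the median of that list. Its remaining members had summed counts no higher than that of Mcm3 (57 UMIs in flox and 71 in cKO). The interferon response was low at −0.61 (Ifitm3 0.15, Bst2 −0.23 and Oasl2 −0.49). The homeostatic microglia (−1.33; Cst3 0.33 and Csf1r −0.86), phagocytosis and complement (−0.41; Stab1 0.35, Pros1 −0.01 and C1qc −0.44), NADPH oxidase (−0.99; Cyba −2.45 and Cybb −0.75) and neutrophil activation (−0.41; Icam1 1.23, Cstb 0.46 and Ccl4 −0.61) lists, mostly of myeloid genes, were low beside a smaller microglia-like share in cKO, and the neutrophil activation median was 0.07 when each cell had equal weight. Immediate early and heat shock genes were low at −0.24 (Zfp36 0.22, Jund −0.36, Fos −0.26 and Hspa8 0.09), but at −0.046 with the median of genes of like GC subtracted and at 0.084 relative to the other classes. Gnb2 (−3.44), Csrp1 (−3.21) and Gpx4 (−3.20) led the lower genes, and the scaling shift of this class was the largest, at 0.14. Of the lower genes of this class, 60.9% were among the shared lower genes. Cldn5 was not among the 332 shared lower genes. It was also not among the 8 genes found at least 2-fold lower relative to the other classes. That ratio could not be formed for 17 of the genes past the size rule in this class. Cldn5 is an endothelial marker, and in other classes it may be too low or come from leaked RNA. The class-relative ratio therefore decides nothing about Cldn5.

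Oligodendrocyte-like cells, the myelin-forming class, had 5 genes higher and 70 lower. The TWEAK receptor Tnfrsf12a was at 66.2 and 165 CPM (1.32), the nuclear RNA Neat1 at 121 and 280.1 CPM (1.21) and Lgals3, abundant in phagocytes, at 85.9 and 230.1 CPM (1.42). Gnb2 (−3.00), Csrp1 (476 and 68.9 CPM, −2.79) and the proteasome subunit Psmd3 (107 and 17.1 CPM, −2.64) were lower. All 5 extreme lists were high: MHC class II (0.80; Cd74 0.92 and H2-Ab1 0.93), cell cycle (0.51; Stmn1 −0.37, Pcna −0.04, Hmgb2 −0.23 and Mcm5 −0.10), immediate early and heat shock (0.20; Hspa8 0.04, Hsp90aa1 0.28 and Fos −0.23), neutrophil activation (0.46; Cstb 0.35, Csf1 −0.06, Ccl4 −0.55 and Ccl3 −0.31) and activated endothelium (0.70; Apln 0.04, Plvap −0.03 and Icam1 0.57). The MHC class II median changed sign when each cell had equal weight (−0.03). So did the cell cycle median among members with at least 50 UMIs (−0.04) and the neutrophil activation median with doublets kept (−0.03). A cluster with the heat shock genes Hspa1b and Cryab among its top genes held 54 flox and 87 cKO cells. The make-up of the class thus differed for these genes.

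Over all cells pooled 10 of 28 lists were extreme. Fatty acid uptake and binding (0.21; Fabp5 0.36, Msr1 0.23 and Lrp1 −1.82), oxidative phosphorylation (0.15 by median and −0.19 by mean; Cox7c 0.15 and Cox6b1 0.25), antioxidant response (0.23; Gpx1 0.22 and Prdx1 0.05), activated endothelium (0.65; Icam1 0.12, Lrg1 0.06 and Vcam1 −0.05) and reactive astrocyte genes (0.43; Vim 0.41, Cd14 0.05 and Emp1 −0.17) were high. Glycolysis and hypoxia response (−0.14; Gapdh 0.24, Aldoa 0.20, Pgam1 0.27 and Pgk1 0.03), interferon response (−0.44; Ifitm3 0.07, Bst2 −0.18 and Ifi27l2a −0.54), homeostatic microglia (−0.56; Cst3 0.22, Csf1r 0.18 and Olfml3 −0.24), NADPH oxidase (−0.23; Cybb −0.23 and Rac2 0.20) and immediate early and heat shock genes (−0.41; Zfp36 0.00, Fos −0.49 and Hspa8 0.07) were low. The lists closest to the lipid droplet were not extreme, with medians of −0.08 for lipid droplet and triglyceride synthesis, −0.01 for lipolysis, 0.13 for fatty acid oxidation, −0.13 for fatty acid synthesis, 0.10 for cholesterol synthesis and 0.10 for cholesterol efflux and storage. The immune lists stood at −0.07 for inflammatory cytokines and chemokines, −0.03 for disease-associated microglia, −0.11 for MHC class II, −0.04 for MHC class I, −0.05 for phagocytosis and complement, 0.01 for repair-associated macrophage and 0.06 for lysosome. The cell cycle was at 0.09, neutrophil granule at 0.02, neutrophil activation at 0.12, blood-brain barrier endothelium at −0.03 and lymphocyte effector at −0.10. Median and mean differed in sign for fatty acid oxidation (mean −0.07), lysosome (−0.15), neutrophil granule (−0.41) and repair-associated macrophage (−0.02). About 1.12 of 28 lists would pass either end if members were independent draws, as in the random lists. Members of a real list can vary together and some lists share genes, so more could pass without a difference of the list.

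**Figure D5:**
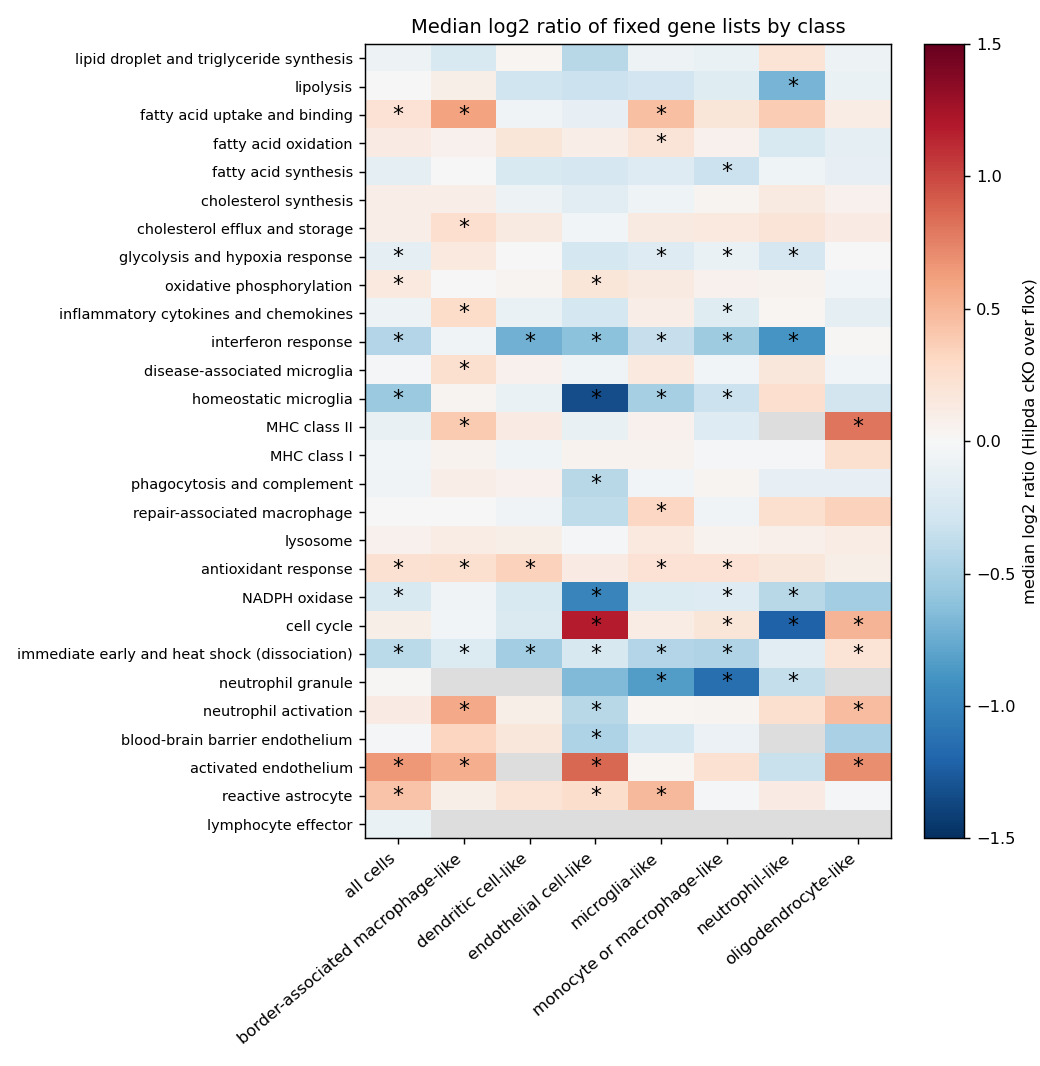
Median log2 ratio (cKO over flox, colour) of 28 fixed gene lists for all cells and 7 compared classes, with stars on medians below the 2nd or above the 98th percentile of matched random lists. Endothelial cell-like cells had the cell cycle list at 1.18 and the homeostatic microglia list at −1.33.

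Haemoglobin genes of red blood cells were lower in cKO, with Hba-a2 at 122 and 17.1 CPM (−2.83) and Hbb-bs at 55.2 and 7.69 CPM (−2.84). Both belong to the shared lower genes, with a 3′ GC of 57.6% and 51.4%. Mitochondrial RNA summed to 67600.0 and 67612 CPM, and ribosomal protein genes to 57919 and 60987 CPM (0.07). Of the ribosomal protein genes 6 were past the size rule as lower in all cells, and in endothelial cell-like cells their sum was 73447 and 95333 CPM (0.38).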

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

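All tests in this part were chosen after the results were seen. Only for 3′ GC content as the whole cause of the shared lower genes was the prediction written before the test. Some values went in opposite directions in different cell classes, and none of these differences between classes was tested. Hilpda was at a log2 ratio of −0.82 in macrophage-like and 1.16 in microglia-like cells. Inflammatory cytokines and chemokines were low in macrophage-like cells (median −0.18) and high in border-associated macrophage-like cells (0.28). Immediate early and heat shock genes, which tissue dissociation induces, were high in oligodendrocyte-like cells (0.20) and low in border-associated macrophage-like (−0.21), dendritic cell-like (−0.52), endothelial cell-like (−0.24), microglia-like (−0.44) and macrophage-like cells (−0.45), but relative to the other classes the border-associated macrophage-like and endothelial cell-like medians reversed (0.10 and 0.084). Neutrophil activation genes were high in border-associated macrophage-like (0.56) and oligodendrocyte-like cells (0.46) and low in endothelial cell-like cells (−0.41), but the oligodendrocyte-like median reversed to −0.032 with doublets kept and the endothelial one to 0.073 with equal weight, so no opposite directions were read. Cell cycle genes were high in endothelial cell-like (1.18), macrophage-like (0.18) and oligodendrocyte-like cells (0.51) and low in neutrophil-like cells (−1.22). The oligodendrocyte-like median reversed to −0.041 among members with at least 50 UMIs. In endothelial cell-like cells the most counted members lay below the median of the list (Pcna 0.23, Stmn1 0.21 and Hmgb2 0.52).

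The opposite Hilpda directions were weighed against a shift of the whole library, a different mix of states and leaked RNA. Relative to the median of the other classes Hilpda was at −1.15 in macrophage-like and 1.28 in microglia-like cells. This argues against a shift of Hilpda alike in every class, but the opposite signs were already seen. Its summed level was also higher in cKO, with intervals excluding equal levels, in border-associated macrophage-like, dendritic cell-like and unnamed cells. So it was, from few flox UMIs, in astrocyte-like, choroid plexus epithelial cell-like and fibroblast-like cells. Neutrophil-like cells were lower, and intervals elsewhere included equal levels. A rise in many classes except macrophage-like and neutrophil-like cells thus stays open. Standardised to the flox make-up over subsets made without the shared genes, the ratios were −0.93 in macrophage-like and 0.91 in microglia-like cells, but over the main clusters they ran from −1.13 (flox make-up) to −0.40 (cKO make-up) and from 0.22 to 1.11, so a different mix of states stays open as part of both, because several main clusters came almost wholly from 1 library. Macrophage markers in microglia-like cells were higher in cKO by a median of 0.20 points of their macrophage-like level, where the Hilpda difference would need 46.5 points, and the highest of 7 markers moved 3.99 points. The genotype and library preparation stay open as untested explanations, and a genotype effect that is opposite in macrophages and microglia may be kept only as a hypothesis.

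The genes at least 2-fold lower in the cKO library in 4 or more classes, among them Gnb2, Eif5a and C1qa, were weighed against 3′ GC content, the genotype and library preparation. A 3′ GC of 50% or more was present in 88.3% of them, in line with a GC-linked difference. After the median of genes of like GC was subtracted, macrophage-like and oligodendrocyte-like ratios still correlated across 926 genes (r 0.650, against 0.675 before), and genes are not independent replicates. The median ratio of genes of like 3′ GC was thus not the whole cause. Genes of like GC differed widely, however. At 55 to 60% GC in macrophage-like cells the median was −0.39, with 30.6% of genes at least 2-fold lower. The subtraction therefore cannot exclude GC acting in another form, such as at the counted site. A genotype acting in myeloid cells alone, with RNA leaking into other cells, would spare genes that oligodendrocyte-like cells express at least as highly, but 234 such genes had a median of −1.41 there. With 1 library per group, library preparation cannot be told apart from a genotype effect in every class.

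The lower Lyz2 and higher Lyz1 in the cKO library were found by an exploratory look, with ranges set afterwards, and Lyz2 was one of the shared lower genes, at −1.21 in endothelial cell-like, −1.498 in oligodendrocyte-like and −0.79 in microglia-like cells as well. Of genes within 2 GC points of Lyz2, 0.929% were 2-fold lower in macrophage-like cells, and Lyz1 UMIs were 2.19% of Lyz2 UMIs in cKO against 0.0591% in flox, which argues against GC content and against a fixed sharing of reads. A driver allele in one copy of Lyz2 in the cKO animal may be kept only as a hypothesis. Lyz2 lay between −1.3 and −0.7 in 4 of 4 myeloid classes (−1.21 to −0.83), but that range was set around values already seen, so it decides nothing. The ratios outside the myeloid classes do not decide it either. Lyz2 in flox was only 541 CPM in oligodendrocyte-like and 447 CPM in endothelial cell-like cells, against 16991 CPM in macrophage-like cells. RNA leaked from macrophages may account for those levels, which was not tested. The labels name no driver. Of 27 genes of like GC at 1000 CPM or more in flox macrophage-like cells, the immediate early gene Nr4a1 was the lowest there (−0.98). Ccl4 was next at −0.48, so Lyz2 (−1.10) lay below all of them. Hilpda was not lower wherever Lyz2 was high, since its highest ratio among such classes was 1.16, in microglia-like cells.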

How the results depend on the processing

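The ratios relative to the other classes, the GC subtraction, the clustering without shared genes and the macrophage-like class without its interferon-led cluster were chosen after the data were seen. Every alternative set before the data were examined was run. No paired analysis was possible because each group has 1 library, so that the groups share fewer than 2 replicate numbers. Of 1251 alternative values over 168 results, 987 stayed within their counting interval or within 1.5 times their count, 239 moved and 25 reversed, and where not stated otherwise the cause was not tested. Hilpda kept its direction in macrophage-like and microglia-like cells under every alternative run for it. These did not include another resolution or thinning before clustering. With the classes of the clustering without shared genes, Hilpda was at −0.82 in macrophage-like and 1.16 in microglia-like cells.

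The microglia-like share in flox and cKO was 29.1% and 22.7% with at least 1000 UMIs per cell, 28.0% and 22.9% with at most 10% mitochondrial UMIs, and 28.5% and 21.8% with cells thinned to 500 UMIs. The macrophage-like share was 47.5% and 46.9%, 50.2% and 49.1%, and 41.1% and 39.6% under the same settings.

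With no minimum CPM the size rule called 378 genes higher and 744 lower in all cells, 68 and 637 in microglia-like cells and 74 and 581 in macrophage-like cells, since more genes could pass. With at most 10% mitochondrial UMIs 2 genes were higher in all cells and 2 in microglia-like cells, and with equal weight per cell 2 were higher in all cells. Relative to the other compared classes 2 genes were higher and 0 lower in microglia-like cells, and 0 and 0 in macrophage-like cells.

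Hilpda in microglia-like cells was at 1.03 with doublets kept, 1.26 with equal weight and 1.28 relative to the other classes. In macrophage-like cells it was at −0.75 with equal weight and −1.15 relative to the other classes. The interferon list was at −0.16 in microglia-like and −0.46 in macrophage-like cells with equal weight. Relative to the other classes it reversed to 0.13 in microglia-like cells and stood at −0.078 in macrophage-like cells, where it was −0.31 without the interferon-led cluster.

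MHC class II in border-associated macrophage-like cells reversed to −0.41 with at least 1000 UMIs, −0.25 with at most 10% mitochondrial UMIs, −0.25 at resolution 0.5 and −0.048 with equal weight. Equal weight also reversed endothelial neutrophil activation (0.073) and oligodendrocyte MHC class II (−0.030). The oligodendrocyte cell cycle reversed at 50 UMIs per member (−0.041), and its neutrophil activation with doublets kept (−0.032).

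Relative to the other classes, immediate early genes reversed in border-associated macrophage-like (0.10) and endothelial cell-like cells (0.084), activated endothelium in border-associated macrophage-like cells (−0.10) and the antioxidant response in dendritic cell-like cells (−0.031). In macrophage-like cells Gnb2 (0.088), Eif5a (0.032), Gas6 (0.037), glycolysis and hypoxia response (0.049), homeostatic genes (0.068), antioxidant genes (−0.017) and NADPH oxidase (0.000274) reversed. Gnb2 in endothelial cell-like cells (0.23), Ftl1-ps1 in microglia-like cells (0.050), and Gnb2 (0.66), Csrp1 (0.20) and Psmd3 (0.29) in oligodendrocyte-like cells did as well. By its construction this ratio removes what the classes share.

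With the median of genes of like 3′ GC subtracted, 53 of 64 extreme list medians stayed within their counting interval and 11 moved, none with a change of sign. The largest of these moves were in endothelial cell-like cells for immediate early genes (−0.046) and oxidative phosphorylation (0.26) and in all cells for activated endothelium (0.81). In microglia-like cells homeostatic genes were at −0.42, and in macrophage-like cells glycolysis and hypoxia response was at −0.14, inflammatory cytokines and chemokines at −0.22 and the antioxidant response at 0.21. In all cells glycolysis and hypoxia response was at −0.19, oxidative phosphorylation at 0.13, the antioxidant response at 0.20 and immediate early genes at −0.45.

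Among the 7 compared classes, neutrophil-like cells had the lowest median depth (1062 and 1292 UMIs), and Hilpda there rested on 50 and 14 UMIs.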

Other observations

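The genes in this part, and the ratio relative to the median of the other compared classes, were chosen after the results were seen. In endothelial cell-like cells of the cKO library the interferon-induced chemokine Cxcl10 was at 156 CPM in flox and 31.0 CPM in cKO (log2 ratio −2.33, and −2.58 relative to the other classes), and the antiviral gene Rsad2 at 111 and 27.5 CPM (−2.02). Spock2, a proteoglycan of brain endothelium, was at 2935 and 1066 CPM (−1.46), but it leads an endothelial cluster that held 212 flox and 80 cKO cells, so the make-up of the class differed too. The growth factor Ptn was at 121 and 44.8 CPM (−1.43). Higher in cKO were the secreted insulin-like growth factor binding protein Igfbp4 (97.97 and 223 CPM, 1.19), the calcium-binding S100a6 (162 and 331 CPM, 1.03) and the growth factor Hbegf (44.9 and 113 CPM, 1.33).

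Other classes had genes apart from the rest as well. Oligodendrocyte-like cells had more of the small heat shock protein gene Cryab (1542 and 2234 CPM, 0.53, against −0.997 in the other classes). Hspa1a (99.5 and 174 CPM, 0.81) and Hspa1b (78.8 and 154 CPM, 0.96) were also higher there. The matrix protein gene Spp1 was lower (443 and 174 CPM, −1.34). Cryab and Hspa1b were among the top genes of an oligodendrocyte-like cluster that held 54 flox and 87 cKO cells. The make-up of the class thus differed too. Border-associated macrophage-like cells had more of the glucocorticoid-induced kinase Sgk1 (94.0 and 206 CPM, 1.13) and the receptor Axl, which binds Gas6 on dying cells (54.8 and 116 CPM, 1.09). Dendritic cell-like cells had less of the cyclin gene Ccnd1 (207 and 104 CPM, −1.0005) and of Icam1 (213 and 141 CPM, −0.60), the latter being higher in endothelial cell-like cells. Pnpla2, the lipase that Hilpda inhibits, was at −1.54 in macrophage-like and −1.51 in microglia-like cells, but also at −1.61 in endothelial cell-like and −1.34 in oligodendrocyte-like cells. It was at least 2-fold lower in all 7 compared classes, with a 3′ GC of 51.8%, and so belongs to the shared lower genes. In microglia-like cells the subset led by Siglech and P2ry12 held 663 flox and 235 cKO cells and the subset led by Mmp12 and Lpl held 526 and 553. These subsets rest on genes that also differ between the libraries, and the counts come from 1 library each.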
